A study of Mus musculus with 20 samples.

How the data were processed

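Bone marrow of C57BL/6 mice was grown into macrophages over 7 to 8 days in medium with 15% L929-conditioned medium, in the presence of 1 µM SGC0946 or of DMSO. Cells were then left unstimulated (4 libraries per arm), given 10 ng/mL LPS for 3 h (3 per arm) or given 2 µM GW3965 for 17 h (3 per arm), which makes 20 libraries in 6 groups. Per the labels, 700 ng of RNA went into each KAPA mRNA HyperPrep library, and reads of 50 bp from 1 end were sequenced on an Illumina HiSeq. By the submitters' processing notes reads were aligned to mm10 with STAR 2.5.2b and handled with SAMtools 1.3.1. The program that counted reads, its annotation and its strand setting are not given in the sources used here. The titles of 6 libraries (DMSO replicates 1 to 3 and DMSO+GW3965 replicates 1 to 3) carry the word reanalyzed. That word sits in the DMSO arm alone. In the GW3965 comparison of SGC0946 it cannot be separated from the inhibitor. In unstimulated cells DMSO replicate 4 lacks it, so it can be separated there only in part. None of the LPS libraries carries it. LPS against unstimulated DMSO cells, and the difference of LPS responses, therefore also set libraries without the word against libraries with it.

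The authors deposited a table in which each value is the count of reads per RefSeq transcript and library. A second deposited table gives the RPKM of the same 35745 transcripts (30745 with NM and 5000 with NR identifiers). The RPKM values were checked to be the counts divided by length and library total, with a relative deviation of at most 5.4e-05 over 778 transcripts with 2000 or more counts. The RPKM table was used here only for an alternative choice of transcripts. Identifiers were joined to symbols of the RefSeq gene table for GRCm38.p6, which named 35440 transcripts. The 305 unnamed transcripts held 1.17% of all counts and were not tested. For the 6035 symbols with more than 1 transcript, the transcript with the highest total count was kept, because summing would count shared reads more than once. This choice was made after the format of the files was seen. The resulting table of 24342 symbols held 57.4% of all counts. Depth per library was 8.17 to 13.33 M counts in this table (median 10.4 M) and 13.94 to 23.11 M over all transcripts. Among 155 genes checked, 10 share 10% or more of their exon length with another annotated gene. Those named in the text are Il1a and Mir5114, and their counts are uncertain for that reason. Counts of close paralogs (Scd1 and Scd2, the H2 genes and Mx1) are uncertain too.

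Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, on all 20 libraries with 1 mean per group, TMM scaling and filterByExpr with a count minimum of 10. This left 12013 genes, with a biological coefficient of variation of 8.87%. Dispersion was pooled over groups, though libraries of a group differed more in the SGC0946 arm. Chi-square per gene between libraries of a group was 3.09 to 6.25 in the DMSO arm and 4.33 to 14.4 in the SGC0946 arm. Errors may thus be too small for SGC0946 cells and too large for DMSO cells. The 9 comparisons were SGC0946 against DMSO in each of the 3 conditions, LPS and GW3965 against unstimulated cells in each arm, and the difference of each response between the arms. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no fold threshold. Fold changes are log2 values with 1 approximate SE, and levels are CPM, counts scaled to library size, with 1 SD over libraries. That SE is the size of the log2 fold change divided by the square root of F. TMM factors were 0.686 to 0.717 in the LPS libraries and 1.14 to 1.19 in the others.

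Gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The 25 lists cover cholesterol biosynthesis, fatty acid synthesis, LXR targets and cholesterol efflux, NF-kB inflammatory genes, the type I interferon response, alternative activation, MHC class II presentation, the DOT1L complex and elongation partners, HOXA and progenitor genes, macrophage identity, lysosome, glycolysis, cell cycle, the unfolded protein and integrated stress response, matrix remodelling and plaque, osteoclast, neutrophil and granulocyte precursor, dendritic cell, B cell, T and NK cell, erythroid, mast cell and basophil, megakaryocyte and platelet, stromal and fibroblast, and immediate early genes. The 20 lists with 5 or more measured members were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with a correlation estimated per list, and fry, which asks whether members move on balance in 1 direction; fry does not compare a list with other genes. Members called were counted with adjustment over all genes and with adjustment over the list alone. Kmt2a, Ighm and Trbc2 are in the lists and not in the table. The rule named up to 5 genes per direction and comparison with the largest fold change among called genes with a mean log2 CPM of 3 or more and groups that did not overlap. It added up to 4 members per list with the smallest p, and Dot1l, Srebf1, Srebf2, Abca1, Abcg1, Tnf, Il1b, Il6, Fasn and others wherever measured. Not all genes it allows are named, and some items are withheld and not reported here.

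A sheet in the series pairs libraries of the same replicate number by animal. The pairing was checked on 8522 genes: libraries of the same number had a median correlation of 0.182 over 46 pairs (35 above 0.1) after removal of group means, other pairs -0.076. In 17 of the 20 libraries the best match had the same number. These pairs include libraries of the same arm. Between unstimulated DMSO and SGC0946 libraries the same-number values were 0.126, 0.135, -0.0288 and -0.044 for replicates 1 to 4. Replicate 4 has no other pair, so the check did not bear out its pairing. DMSO replicate 3 correlated with SGC0946+LPS and SGC0946+GW3965 replicate 3 at 0.00646 and -0.0036. DMSO+GW3965 replicate 3 correlated with SGC0946, SGC0946+LPS and SGC0946+GW3965 replicate 3 at 0.285, 0.167 and 0.212. Across arms the check thus bore out the pairing of replicate 3 only in part. The 6 replicate 1 libraries had Ddx3y at 108 CPM or more and Xist at 0.923 CPM or less. The other 14 had at most 1.19 and at least 456 CPM. Ddx3y and Xist thus set replicate 1 apart and cannot tell replicates 2 to 4 from each other. A fit with the replicate number as a block was run for every result, and its value stands beside a result where it changes a call or moves a count by more than 1.5 times.

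Alternatives planned in advance were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter minimum of 50, thinning to 8.17 M counts, fitting only the compared groups, the replicate block, and leaving out each of the 20 libraries. Scaling by library totals only, choosing transcripts by RPKM, leaving out each of the 4 replicate numbers, and leaving out replicates 2 and 4 together were chosen after the data were seen. The pipeline was tested on simulated data with 50 genes per fold size. At 1.5-fold it recovered 60% in the unstimulated comparison of SGC0946, 58% under LPS and 56% under GW3965. At 2-fold the recovery was 93.9%, 83.7% and 80% in the same order. For GW3965 in DMSO and SGC0946 cells it was 72% and 76% at 1.5-fold, for LPS 72% and 69.4%. For the differences between responses it was 42% (LPS) and 46.9% (GW3965) at 1.5-fold, and 72% and 73.5% at 2-fold. The share of false calls was 2.52% to 10.8% over the 9 comparisons. The simulated counts were drawn gene by gene, with no animal effect and no correlation between genes. Both kinds of share hold for such data and can differ in the libraries used here. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.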

Results

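SGC0946, an inhibitor of the H3K79 methyltransferase DOT1L, was present while bone marrow grew into macrophages. Its effect was read in unstimulated cells (4 animals per arm), after LPS for 3 h (3 per arm) and after the LXR agonist GW3965 for 17 h (3 per arm). Changes are log2 fold changes with 1 SE, and adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Those for lists are from camera. Dot1l itself was measured at 58.5 ± 3.86 CPM in DMSO and 51.9 ± 9.64 CPM in SGC0946 cells, a change of -0.18 ± 0.13 that did not pass the test (edgeR adjusted p = 0.440).

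In unstimulated macrophages grown with SGC0946, genes of sterol synthesis were lower and genes of MHC class II presentation were higher than in DMSO cells, most of all in replicates 2 and 4. Both lists passed at camera's preset correlation and neither with an estimated one (adjusted p = 0.121 for each). Both passed with fry, which does not compare a list with other genes (adjusted p = 0.00584 and 0.00565). Srebf2, which encodes the transcription factor of the sterol pathway, fell by 0.56 ± 0.08, and Ciita, the master regulator of MHC class II genes, rose by 1.33 ± 0.20 (n = 4 against 4). The list of neutrophil and granulocyte precursor genes had the lowest median, and the metalloprotease genes Mmp12 and Mmp13 rose. Of 12013 genes, 546 were higher and 502 lower with SGC0946 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). A change of 2-fold or more was seen in 219 of them, 194 higher and 25 lower.

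Of 25 cholesterol biosynthesis genes, 18 fell, none rose and 7 did not pass the test; adjusted over the list alone, 21 fell. The median change was -0.57 (camera adjusted p = 4.29e-16; adjusted p = 0.121 with an estimated correlation). Insig1, whose product holds the SREBP complex in the endoplasmic reticulum, fell by 0.81 ± 0.13 (edgeR adjusted p = 0.000473). Mvd of the mevalonate pathway fell by 0.73 ± 0.12 (adjusted p = 0.000493). In Srebf2, Insig1 and Mvd every SGC0946 library lay below every DMSO library. The fall was deepest in SGC0946 replicates 2 and 4, whose list medians were -0.83 and -0.82 against DMSO, while those of replicates 1 and 3 were -0.30 and -0.34. With those 2 replicates left out the list median was -0.23, camera's adjusted p was 1.04e-10, and 3 of the 25 members fell. Among 20 fatty acid synthesis genes 6 fell (11 adjusted over the list alone; 10 with the replicate block), with a median of -0.23 (adjusted p = 6.56e-06; adjusted p = 0.142 with an estimated correlation). Acsl3 fell by 0.71 ± 0.12 and Acss2 by 0.44 ± 0.08 (edgeR adjusted p = 0.00049 and 0.00125). Fasn was at 122 ± 39.0 CPM against 184 ± 17.2 CPM and did not pass (adjusted p = 0.116; 0.0198 with the replicate block; 0.0350 with no filter on low counts; 0.0457 with only the compared groups; 0.0351 without SGC0946 replicate 1). The median of this list was -0.12 without replicates 2 and 4 (adjusted p = 0.0296, 1 member higher and 1 lower).

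MHC class II presentation rose as a list, with 8 of 12 members higher (10 adjusted over the list alone) and a median of 0.53 (adjusted p = 1.44e-08; adjusted p = 0.121 with an estimated correlation). Cd74, the invariant chain, went from 147 ± 27.9 to 289 ± 63.1 CPM, a rise of 0.98 ± 0.18 (edgeR adjusted p = 0.00157). H2-Ab1 rose by 1.06 ± 0.24 (adjusted p = 0.00675), a value that without replicate 4 was 0.79 (adjusted p = 0.113). These genes too were highest in SGC0946 replicates 2 and 4, with list medians of 0.62 and 0.80 against 0.28 and 0.46 in replicates 1 and 3. Left without replicates 2 and 4, the list had a median of 0.25 (adjusted p = 0.0137) and 1 member rose. Dendritic cell genes, which overlap in function with antigen presentation, had a median of 0.56 (adjusted p = 0.00078; adjusted p = 0.0879 with an estimated correlation) and 3 of 8 members rose. Cd24a was the member with the smallest p, at a rise of 0.99 ± 0.12 (edgeR adjusted p = 1.12e-05).

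The list of neutrophil and granulocyte precursor genes fell, with a median of -2.64 (camera adjusted p = 8.6e-27; adjusted p = 0.000605 with an estimated correlation). Of its 16 genes 7 were measured, and 5 of them fell. The other measured members stayed near their DMSO levels. Csf3r was at 57.8 ± 4.96 CPM in DMSO and 55.0 ± 13.2 CPM in SGC0946 cells. Mmp8 was at 32.95 ± 3.67 and 31.08 ± 1.51 CPM in the same order. S100a9 fell by 3.17 ± 0.26, from 11.8 ± 1.92 to 1.26 ± 0.777 CPM, and Ngp fell by 3.33 ± 0.27 (edgeR adjusted p = 2.14e-07 for both). Ltf fell by 2.52 ± 0.27 and Lcn2 by 3.56 ± 0.28 (adjusted p = 5.41e-06 and 1.67e-07). The medians of the 4 SGC0946 libraries lay between -2.77 and -2.07, so the fall was seen in each of the 4 animals. Without replicates 2 and 4 the median was -2.98 and 6 members fell (adjusted p = 1.64e-43).

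Matrix remodelling genes rose in 5 of 19 cases (6 adjusted over the list alone), with a median of 0.32 (adjusted p = 9.78e-05; adjusted p = 0.121 with an estimated correlation). The macrophage elastase gene Mmp12 rose by 1.05 ± 0.20, to 594 ± 170 CPM, and the collagenase gene Mmp13 by 1.27 ± 0.14 (edgeR adjusted p = 0.00219 and 7.64e-06). Fibronectin, Fn1, rose by 2.26 ± 0.35 from a low level of 0.872 ± 0.361 CPM (adjusted p = 0.000293). This list's median was 0.02 without replicates 2 and 4 (adjusted p = 0.0137), and 2 members rose. Osteoclast genes had a median of 0.17 with 2 of 7 members higher (adjusted p = 0.0299; adjusted p = 0.142 with an estimated correlation), and the call was lost without DMSO replicate 2 (0.0583) and without SGC0946 replicate 3 (0.120). Among alternative activation genes, which did not pass as a list (median 0.11, adjusted p = 0.543), 3 rose and 2 fell. The beta-glucan receptor gene Clec7a rose by 0.98 ± 0.09, while Chil3 fell by 1.64 ± 0.19 and the scavenger receptor gene Stab1 fell by 0.54 ± 0.09 (edgeR adjusted p = 9.21e-07, 9.35e-06 and 0.000535). Outside the lists, Ppp1r9a rose by 2.27 ± 0.27, Mgll, a lipase of monoacylglycerols, by 1.60 ± 0.15, and Mamdc2 reached 48.6 ± 6.71 CPM from 17.2 ± 1.11 CPM. The sortilin gene Sort1 fell by 1.20 ± 0.08 and Panx1, a channel gene, by 1.22 ± 0.12, and in each of these 5 genes the groups did not overlap.

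Other lists did not pass or passed without called members. Cell cycle genes had a median of -0.30 over 35 genes (adjusted p = 3.4e-06; adjusted p = 0.639 with an estimated correlation) and no member passed edgeR's test, over all genes or over the list alone, while 5 fell with the replicate block. Without replicates 2 and 4 that median was 0.07 (adjusted p = 0.278), and the library medians were -0.69 and -0.52 in SGC0946 replicates 2 and 4 against -0.07 and 0.02 in replicates 1 and 3. LXR targets had a median of 0.16 (adjusted p = 0.292), with 4 members higher and 2 lower. Abca1 changed by 0.23 ± 0.11 (edgeR adjusted p = 0.201) and Abcg1 by 0.20 ± 0.06 (adjusted p = 0.0571; 0.0264 with the replicate block; 0.0412 without SGC0946 replicate 4), and neither passed. Abcg1 did pass with DESeq2 (0.0228), limma-voom (0.0403), the stricter filter on low counts (0.0451) and library totals only (0.0339). NF-kB genes did not pass, with a median of 0.05, a mean of 0.09 and a camera direction of down (adjusted p = 0.543), and 2 of 27 members fell. Tnf, at 7.19 ± 0.777 and 5.17 ± 1.92 CPM, did not pass (edgeR adjusted p = 0.0929; 0.0249 with DESeq2; 0.0443 with no filter on low counts; 0.00368 without SGC0946 replicate 3). Interferon genes had a median of -0.09, a mean of 0.03 and a camera direction of up (adjusted p = 0.847; 0.000709 up without DMSO replicate 2; 0.0135 down without DMSO replicate 4), and 1 of 36 members rose. The glycolysis list had a median of 0.11 (adjusted p = 0.0707; 0.0468 with the replicate block; 0.0251 without DMSO replicate 3; 0.0107 without SGC0946 replicate 1).

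The remaining lists did not pass in unstimulated cells. Macrophage identity genes had a median of 0.07 (adjusted p = 0.543), with 4 of 25 higher and 2 lower, and genes of the DOT1L complex one of -0.01 (adjusted p = 0.847). HOXA and progenitor genes had a median of -0.35 (adjusted p = 0.537), lysosome genes -0.05 and immediate early genes 0.02 (adjusted p = 0.543 for both). For the unfolded protein response the median was below 0.001 in size while its mean was 0.03 and camera's direction down (adjusted p = 0.564). Megakaryocyte genes had a median of -0.05, a mean of 0.07 and a direction of down (adjusted p = 0.869). Of markers of other cells, 3 of 12 B cell genes were measured and Cd22 rose by 0.54 ± 0.11, and 3 of 14 T and NK cell genes were measured and Cd4 rose by 0.74 ± 0.13 (edgeR adjusted p = 0.00273 and 0.0013). No erythroid gene was measured, and none of 2 mast cell and 3 stromal genes passed (Kit 0.0785; 0.0243 with the replicate block).

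The count of changed genes moved with single libraries. It was 599 without DMSO replicate 4, 673 without SGC0946 replicate 2 and 578 without SGC0946 replicate 4. Leaving out both libraries of a replicate gave 669, 698, 695 and 339 genes for replicates 1 to 4. Without replicates 2 and 4 it was 235 (136 higher, 99 lower), of which 201 were among the 1048. The share of higher genes among those called, 52.1% with TMM, was 62.6% with library totals only (634 higher, 378 lower).

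**Figure D1:**
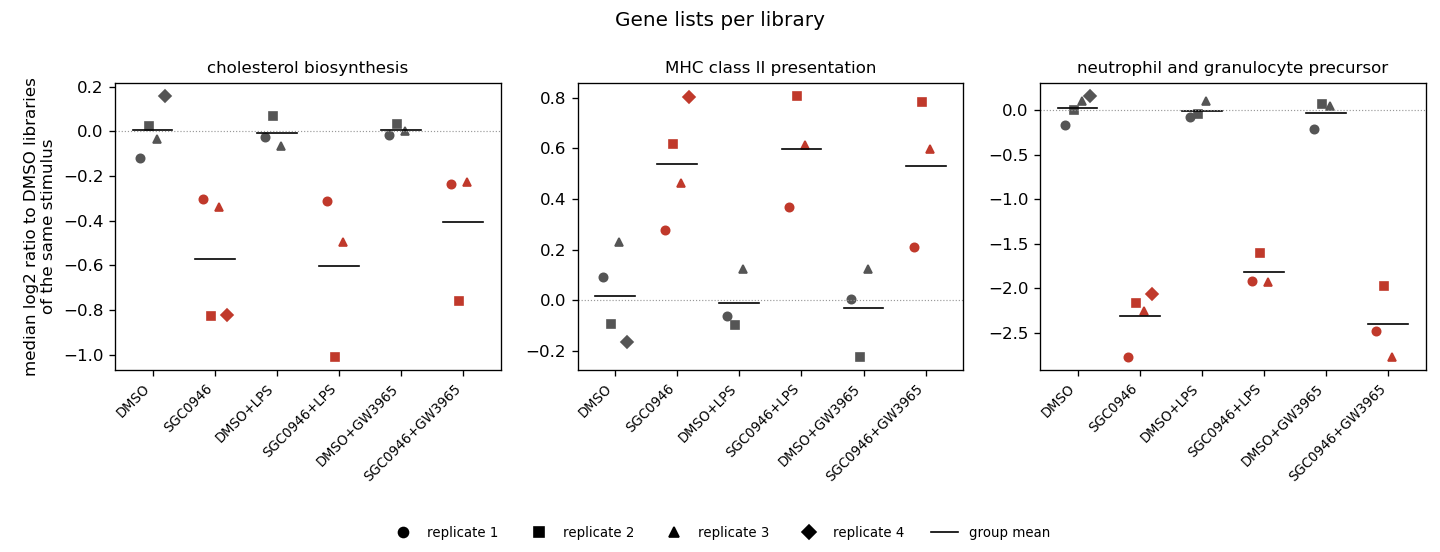
Median log2 ratio of the cholesterol biosynthesis, MHC class II and neutrophil lists to the DMSO libraries of the same stimulus, 1 point per library with marker shape giving the replicate number and lines giving group means. The SGC0946 libraries lay below DMSO for cholesterol genes (-0.83 in replicate 2) and neutrophil genes, and above for MHC class II genes (0.80 in replicate 4).

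After LPS, SGC0946 cells again had lower sterol and granulocyte genes and higher MHC class II genes than DMSO cells (n = 3 against 3). Of these lists that of granulocyte genes passed with an estimated correlation (adjusted p = 0.0137), and those of sterol and MHC class II genes did not (0.170 and 0.129). Mvd fell by 0.96 ± 0.17, Ciita rose by 1.01 ± 0.19 and Mmp13 by 0.88 ± 0.14. Tnf, at 2403 ± 144 CPM in SGC0946 and 2660 ± 103 CPM in DMSO cells, did not pass (adjusted p = 0.573). The inhibitor changed 856 genes, 464 of them higher (edgeR quasi-likelihood, adjusted p under 0.05). A change of 2-fold or more was seen in 172 of them, 155 higher and 17 lower.

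Of 25 cholesterol biosynthesis genes 9 fell and none rose (19 fell adjusted over the list alone; 14 with the replicate block), with a median of -0.60 (camera adjusted p = 6.87e-14; adjusted p = 0.170 with an estimated correlation). Mvd had an edgeR adjusted p of 0.000914. Srebf2 fell by 0.41 ± 0.10 (adjusted p = 0.0133; 0.0585 without SGC0946+LPS replicate 3). The list median of SGC0946+LPS replicate 2 was -1.01 against DMSO, and those of replicates 1 and 3 were -0.31 and -0.50. Without replicate 2 the median was -0.37 (adjusted p = 1.43e-08) and 2 members fell. Fatty acid synthesis did not pass as a list (median -0.21, adjusted p = 0.0547; 0.0348 with the replicate block), and 2 members fell. It passed without DMSO+LPS replicate 2 (0.0447), DMSO+LPS replicate 3 (0.044), SGC0946+LPS replicate 1 (0.00747) or SGC0946+LPS replicate 3 (0.0123). Of these Acss2 fell by 0.65 ± 0.11 (edgeR adjusted p = 0.000796).

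MHC class II genes rose in 8 of 12 cases (11 adjusted over the list alone), with a median of 0.59 (adjusted p = 5.92e-09; adjusted p = 0.129 with an estimated correlation). Ciita rose to 62.1 ± 12.4 CPM (edgeR adjusted p = 0.00263), and the costimulatory gene Cd86 rose by 0.50 ± 0.10 (adjusted p = 0.00511). Cd74 rose by 0.91 ± 0.21 (adjusted p = 0.00956), a call lost without DMSO+LPS replicate 2 (0.0624) or SGC0946+LPS replicate 2 (0.0534). Without replicate 2 the list median was 0.39 (adjusted p = 2.53e-05) and 2 members rose. Dendritic cell genes had a median of 0.48 (adjusted p = 0.00474; adjusted p = 0.124 with an estimated correlation), with 2 of 8 higher (4 with the replicate block). Cd24a rose by 1.12 ± 0.15 (edgeR adjusted p = 8.78e-05), as did Irf4 by 1.40 ± 0.26 (adjusted p = 0.0018). Granulocyte genes had a median of -2.05 (camera adjusted p = 6.09e-15; adjusted p = 0.0137 with an estimated correlation) and 5 of 7 fell. S100a8 fell by 2.05 ± 0.36 and S100a9 by 2.38 ± 0.29 (edgeR adjusted p = 0.00107 and 5.13e-05), and the medians of the 3 SGC0946+LPS libraries were -1.92, -1.60 and -1.93.

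Matrix remodelling genes had a median of 0.10 (adjusted p = 0.0222; adjusted p = 0.397 with an estimated correlation) and 4 of 19 rose. The list call was lost without DMSO+LPS replicate 1 (0.0812) or SGC0946+LPS replicate 2 (0.160). Mmp13 stood at 4433 ± 382 CPM with SGC0946 against 2403 ± 269 CPM (edgeR adjusted p = 0.000387), and Mmp12 rose by 1.08 ± 0.23 (adjusted p = 0.00619). Osteoclast genes had a median of 0.46 (adjusted p = 0.0071; adjusted p = 0.124 with an estimated correlation), with 2 of 7 higher (4 with the replicate block). NF-kB genes had a median of 0.03 and a camera direction of down (adjusted p = 0.922), and 1 of 27 fell (3 lower and 1 higher with the replicate block). Il1b changed by 0.18 ± 0.15 (edgeR adjusted p = 0.540), and Il6 was at 447 ± 84.7 against 381 ± 26.5 CPM (adjusted p = 0.247; 0.0193 without SGC0946+LPS replicate 2). Among interferon genes (median 0.09, adjusted p = 0.151) Ifi44, an interferon-induced gene, rose by 0.95 ± 0.17 and Cxcl9 by 0.57 ± 0.11 (edgeR adjusted p = 0.00109 and 0.00303). Of the stress response genes 3 rose and 1 fell. Trib3, at 7.59 ± 8.09 against 2.00 ± 0.085 CPM with overlapping groups, passed (adjusted p = 0.0391). It no longer passed with limma-voom (0.257) or only the compared groups (0.112), without SGC0946+LPS replicate 2 (0.619) or without any 1 of the 3 DMSO+LPS libraries (0.105, 0.129 and 0.0878 for replicates 1 to 3).

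Clec7a rose by 0.80 ± 0.11 and Stab1 fell by 0.80 ± 0.10 (edgeR adjusted p = 0.000122 and 7.63e-05), and Chil3 fell by 1.68 ± 0.23 (adjusted p = 0.000112). Ppp1r9a rose by 2.23 ± 0.37 and Mgll by 1.52 ± 0.21, Rasgrp1, a Ras activator, reached 57.2 ± 3.40 CPM, while Sort1 fell by 1.17 ± 0.10. The glycolytic gene Hk1 fell by 0.53 ± 0.08 (adjusted p = 0.000269). Cd22 rose by 0.63 ± 0.14 (adjusted p = 0.00923; 0.0524 at equal depth; 0.0514 without SGC0946+LPS replicate 2; 0.05 without DMSO+LPS replicate 2), and Cd4 and Lck rose by 0.91 ± 0.18 and 0.92 ± 0.20 (adjusted p = 0.00355 and 0.00844; Lck 0.0516 without DMSO+LPS replicate 2). No further B cell, T and NK cell, mast cell or stromal gene passed. Cell cycle genes had a median of -0.12 (adjusted p = 0.151; 0.044 without DMSO+LPS replicate 3; 0.00987 without SGC0946+LPS replicate 3). Lysosome genes had a median of -0.07 (adjusted p = 0.151). LXR targets had a median of -0.04, a mean of 0.08 and a direction of up (adjusted p = 0.922), and Abca1 and Abcg1 changed by -0.04 ± 0.12 and -0.01 ± 0.07. The count of changed genes was 527 without DMSO+LPS replicate 1 and 432 without DMSO+LPS replicate 2. Leaving out all libraries of replicate 1, 2 or 3, in all 6 groups, gave 308, 432 and 372 genes.

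In cells treated with GW3965, SGC0946 gave lower granulocyte genes and higher MHC class II genes, with fewer called genes (n = 3 against 3). The MHC class II list did not pass with an estimated correlation (adjusted p = 0.254), and 3 of its 12 members rose (6 with the replicate block), none without replicate 2. Ltf, the lactoferrin gene, was at 0.177 ± 0.0792 CPM with SGC0946 and 6.73 ± 1.55 CPM with DMSO. Ciita rose by 1.31 ± 0.25 and Mmp13 by 1.39 ± 0.17. With the inhibitor 269 genes were higher and 168 lower (edgeR quasi-likelihood, adjusted p under 0.05; 703 genes with the replicate block). A change of 2-fold or more was seen in 151 of them, 133 higher and 18 lower.

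Granulocyte genes had a median of -2.88 (camera adjusted p = 9.38e-34; adjusted p = 0.000202 with an estimated correlation) and 5 of 7 fell (6 adjusted over the list alone). S100a9 fell by 2.88 ± 0.30 and Ngp by 4.18 ± 0.39 (edgeR adjusted p = 9.67e-06 and 2.65e-06). Cholesterol biosynthesis genes had a median of -0.41 (adjusted p = 3.04e-09; adjusted p = 0.308 with an estimated correlation), and 2 of 25 fell (11 adjusted over the list alone; 6 with the replicate block). Srebf2 changed by -0.34 ± 0.10 and did not pass (edgeR adjusted p = 0.0554; 0.0217 with the replicate block; 0.0251 with DESeq2; 0.0400 with limma-voom; 0.0194 with no filter on low counts; 0.0108 without SGC0946+GW3965 replicate 3). The list median of SGC0946+GW3965 replicate 2 was -0.76 against DMSO, and those of replicates 1 and 3 were -0.24 and -0.23. Without replicate 2 the median was -0.26 (adjusted p = 3.65e-05) and no member passed. Fatty acid synthesis had a median of -0.10 (adjusted p = 0.0128; adjusted p = 0.464 with an estimated correlation; 0.163 without SGC0946+GW3965 replicate 2), and 2 members fell.

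MHC class II genes had a median of 0.52 (adjusted p = 7.98e-07; adjusted p = 0.254 with an estimated correlation), with 3 of 12 higher (9 adjusted over the list alone; 6 with the replicate block). Ciita had an edgeR adjusted p of 0.00418. H2-Aa was at 61.2 ± 13.5 against 36.0 ± 8.25 CPM (adjusted p = 0.0604; 0.0161 with the replicate block; 0.0105 with no filter on low counts; 0.0324 without SGC0946+GW3965 replicate 1). Without replicate 2 the list median was 0.31 (adjusted p = 0.00416) and no member rose. Interferon genes had a median of 0.37 (adjusted p = 1.93e-06; adjusted p = 0.464 with an estimated correlation; 0.0539 without SGC0946+GW3965 replicate 1), and 1 of 36 rose. That gene was Ifi44, with a rise of 1.55 ± 0.30 (edgeR adjusted p = 0.00425). Cell cycle genes had a median of -0.33 with no member called, or 2 lower with the replicate block (adjusted p = 1.31e-08; adjusted p = 0.464 with an estimated correlation). Their library medians were -0.23, -0.81 and -0.01 in SGC0946+GW3965 replicates 1 to 3, and without replicate 2 the median was -0.09 (adjusted p = 0.0235). Matrix remodelling genes had a median of 0.22 (adjusted p = 0.0044; adjusted p = 0.284 with an estimated correlation), with 4 higher and 1 lower. Mmp13 had an edgeR adjusted p of 4.75e-05.

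Osteoclast genes had a median of 0.24 with no member called, or 2 higher with the replicate block (adjusted p = 0.0128; adjusted p = 0.225 with an estimated correlation), and the call was lost without SGC0946+GW3965 replicate 3 (0.0955). Dendritic cell genes had a median of 0.49 (adjusted p = 0.0128; adjusted p = 0.225 with an estimated correlation; 0.0818 without DMSO+GW3965 replicate 1), and Cd24a rose by 0.99 ± 0.13. LXR targets, the genes that GW3965 acts on, had a median of 0.15 (adjusted p = 0.115; 0.0142 without DMSO+GW3965 replicate 1; 0.0337 without SGC0946+GW3965 replicate 3), and 1 of 17 rose (2 with the replicate block). Abca1 stood at 2612 ± 482 CPM with SGC0946 and 2357 ± 89.7 CPM without (edgeR adjusted p = 0.598), and Abcg1 at 1466 ± 137 and 1295 ± 54.0 CPM (adjusted p = 0.210). Mgll rose by 1.87 ± 0.19 and Clec7a by 0.90 ± 0.11, while Sort1 fell by 1.18 ± 0.09 and Fkbp5, a glucocorticoid-responsive gene, by 1.40 ± 0.23. Cd22 rose by 0.72 ± 0.13 and Cd4 by 0.78 ± 0.16 (edgeR adjusted p = 0.00183 and 0.00565). Kit, a mast cell and progenitor gene, passed with overlapping groups (0.94 ± 0.26, adjusted p = 0.0465). It no longer passed with limma-voom (0.0699), the stricter filter (0.0521) or only the compared groups (0.103), without DMSO+GW3965 replicate 1, 2 or 3 (0.170, 0.0778 and 0.136), or without SGC0946+GW3965 replicate 1 or 3 (0.110 and 0.181). The other markers of B, T, mast and stromal cells did not pass. The count of changed genes was 260, 232 and 249 without DMSO+GW3965 replicate 1, 2 or 3, and 271 without SGC0946+GW3965 replicate 2. It was 164 when only the compared groups were fitted.

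No gene called with SGC0946 in 2 of the 3 conditions had opposite signs in those 2. In both unstimulated and LPS cells 201 genes were higher and 159 lower, against 21.1 and 16.4 if calls were independent. For unstimulated and GW3965 cells these counts were 219 and 129 (12.2 and 7.02 if independent), and for LPS and GW3965 cells 142 and 85 (10.4 and 5.48). Of the genes, 126 were higher and 78 lower in each of the 3 conditions, among them Ppp1r9a, Mgll, Clec7a, Cd24a and Mmp13 (higher) and Sort1, Stab1, Chil3, S100a9 and Ngp (lower). Fold changes of all genes correlated at 0.565 between unstimulated and LPS cells, 0.673 between unstimulated and GW3965 cells and 0.497 between LPS and GW3965 cells (Pearson). The 3 contrasts share no library, though replicates share animals. After removal of group means, unstimulated SGC0946 replicates 1 to 3 correlated with their LPS libraries at 0.332, 0.426 and 0.304. With their GW3965 libraries the values were 0.452, 0.686 and 0.44. The 3 contrasts are therefore not independent replications. None of the LPS libraries carries the word reanalyzed in its title. Of genes called in unstimulated cells, 93.5% had the same sign under LPS and 98.5% under GW3965. Of genes called under LPS, 86% had the same sign under GW3965. These shares cannot separate the word from the inhibitor.

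**Figure D2:**
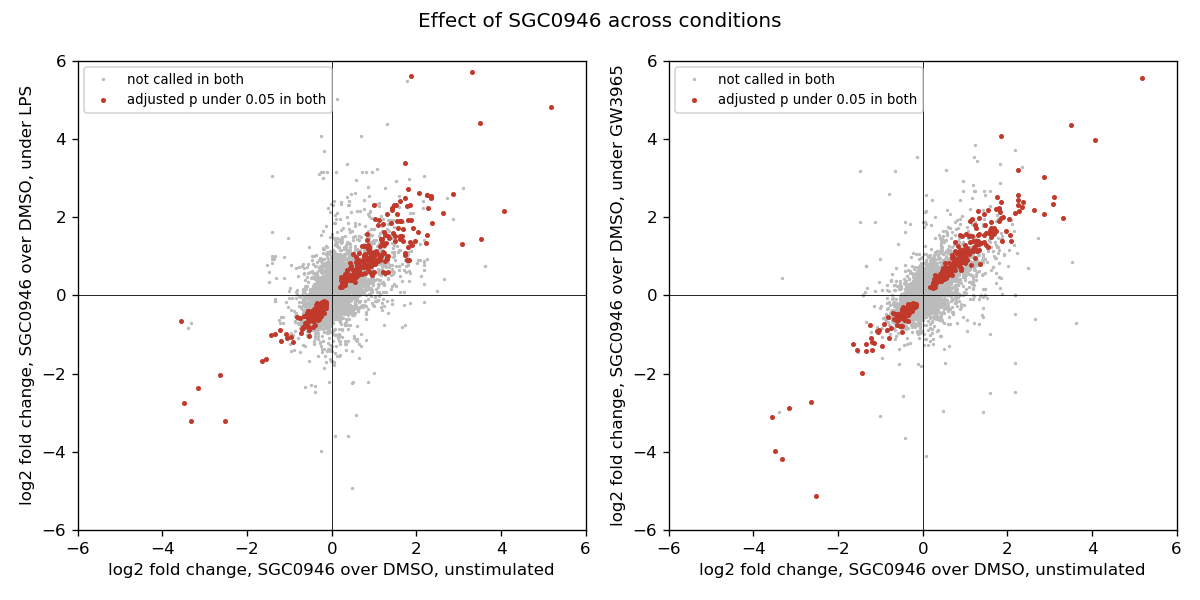
Log2 fold change of SGC0946 over DMSO in unstimulated cells (horizontal) against LPS-treated or GW3965-treated cells (vertical), 1 point per gene, red for genes called in both. Red points lie in the quadrants of equal sign, 201 higher and 159 lower for LPS and 219 higher and 129 lower for GW3965.

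LPS changed most of the measured genes in DMSO cells within 3 h (n = 3 against 4). Each of 27 NF-kB inflammatory genes and each of 36 interferon genes rose. Tnf went from 7.19 ± 0.777 to 2660 ± 103 CPM, and Il6 from 0.129 ± 0.0945 to 381 ± 26.5 CPM. Of 12013 genes 4253 were higher and 4650 lower (edgeR quasi-likelihood, adjusted p under 0.05), 1910 and 2150 of them by 2-fold or more. These directions are relative to TMM scaling. With library totals only the median of all genes moved from -0.07 to -0.80, and 1980 genes were higher and 8674 lower.

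NF-kB genes had a median of 6.63 (camera adjusted p = 1.63e-50; adjusted p = 7e-07 with an estimated correlation). Il1b rose by 9.37 ± 0.23 and Nfkbia, which encodes an inhibitor of NF-kB, by 4.94 ± 0.07 (edgeR adjusted p = 1.69e-19 and 1.16e-22). Ptgs2 rose to 1282 ± 45.4 CPM and Nos2 to 1743 ± 218 CPM, from levels below 1 CPM. Interferon genes had a median of 4.73 (adjusted p = 6.82e-19; adjusted p = 0.329 with an estimated correlation). Cxcl10 reached 9834 ± 174 CPM, a rise of 9.92 ± 0.24, and Irf1 rose by 5.06 ± 0.11 (adjusted p = 2.04e-19 and 1.74e-20). Mmp13 rose by 7.42 ± 0.16, and the glycolytic genes Hk2 and Pfkfb3 rose by 2.57 ± 0.13 and 2.59 ± 0.09. Among sterol genes 8 rose and 6 fell; Srebf2 rose by 0.67 ± 0.09 (-0.06 with library totals only), while Dhcr7, of the last step, fell from 56.0 ± 4.10 to 22.7 ± 3.23 CPM. Among fatty acid genes 2 rose and 9 fell, with Lpin1 falling by 5.31 ± 0.11 and Acsl3 by 2.53 ± 0.16.

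Of LXR targets 4 rose and 4 fell, and the receptor gene Nr1h3 rose by 1.93 ± 0.12. Abcg1 changed by 0.31 ± 0.07 (edgeR adjusted p = 0.000321), a direction that turned to -0.42 with library totals only. Abca1 did not pass (-0.09 ± 0.12, adjusted p = 0.504; -0.82 with library totals only, adjusted p = 4.83e-07). In the DOT1L complex list 7 genes rose and 5 fell, with Ell2 and Mllt6 higher by 2.73 ± 0.12 and 2.47 ± 0.07 and Ell lower (-2.25 ± 0.09). Dot1l changed by 0.22 ± 0.14 (adjusted p = 0.166; 0.00403 with only the compared groups; -0.51 with library totals only). Macrophage identity genes rose in 16 and fell in 6 of 25 cases; Cd14, the LPS co-receptor, rose by 3.40 ± 0.09, and the myeloid factor Cebpa fell by 5.87 ± 0.12. MHC class II genes rose in 9 of 12 cases and cell cycle genes fell in 18 of 35, with Bub1b falling by 1.98 ± 0.19. None of these lists passed camera, which compares them with other genes (adjusted p = 0.893 for cholesterol, 0.147 for fatty acid, 0.716 for LXR, 0.418 for DOT1L complex, 0.332 for macrophage identity and MHC class II, 0.191 for cell cycle and 0.141 for glycolysis). The other lists did not pass either, with HOXA genes at 1 higher and 7 lower of 9 (adjusted p = 0.475) and osteoclast genes at 2 higher and 3 lower of 7 (adjusted p = 0.995). Of B cell genes all 3 measured fell, and of 3 stromal genes 2 rose.

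In SGC0946 cells the LPS response had the same main features (n = 3 against 4). Of 12013 genes 4296 were higher and 4666 lower (edgeR quasi-likelihood, adjusted p under 0.05), and 1977 higher and 8699 lower with library totals only. NF-kB genes rose in 27 of 27 cases with a median of 6.59 (camera adjusted p = 1.7e-49; adjusted p = 7.71e-08 with an estimated correlation). Interferon genes rose in 36 of 36 cases with a median of 4.93 (adjusted p = 3.36e-19; adjusted p = 0.423 with an estimated correlation). Tnf rose by 8.88 ± 0.17 and Il1b by 8.77 ± 0.21, and Il6 reached 447 ± 84.7 CPM. Srebf2 rose by 0.82 ± 0.09 (0.08 with library totals only). Abca1 fell by 0.35 ± 0.12 (edgeR adjusted p = 0.00909; groups overlapped). Abcg1 changed by 0.10 ± 0.07 and Dot1l by 0.12 ± 0.14, neither of which passed, and both turned with library totals only (-0.64 and -0.62). Cebpa fell by 6.41 ± 0.13, and Cnr2, a cannabinoid receptor gene, by 6.65 ± 0.17. No further list passed camera.

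The LPS response differed with SGC0946 for 1 gene of 12013 (edgeR quasi-likelihood), while 835 had an unadjusted p under 0.05. Lcn2, which encodes lipocalin-2, rose from 0.252 ± 0.0899 to 11.3 ± 2.34 CPM with the inhibitor and from 3.16 ± 0.702 to 17.9 ± 1.03 CPM without, a difference of 2.89 ± 0.34 (adjusted p = 0.000395). This log2 difference rests on a low baseline, as Lcn2 lay at 0.174 to 0.356 CPM in the unstimulated SGC0946 libraries. The call of Lcn2 was lost without replicate 2 (0.0642) or replicate 3 (0.174). DESeq2 called 37 genes, limma-voom 1 and the replicate block 6, and the count was 11 without SGC0946+LPS replicate 2 and 2 without SGC0946 replicate 3, DMSO+LPS replicate 3, SGC0946+LPS replicate 1 or SGC0946+LPS replicate 3. The differences of Tnf (0.35 ± 0.22), Il1b (-0.60 ± 0.40) and Abca1 (-0.27 ± 0.16) did not pass (adjusted p = 0.830, 0.843 and 0.810). Elovl6, a fatty acid elongase gene, had a difference of 1.76 ± 0.38 that did not pass (adjusted p = 0.151; 0.0256 with no filter on low counts).

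**Figure D3:**
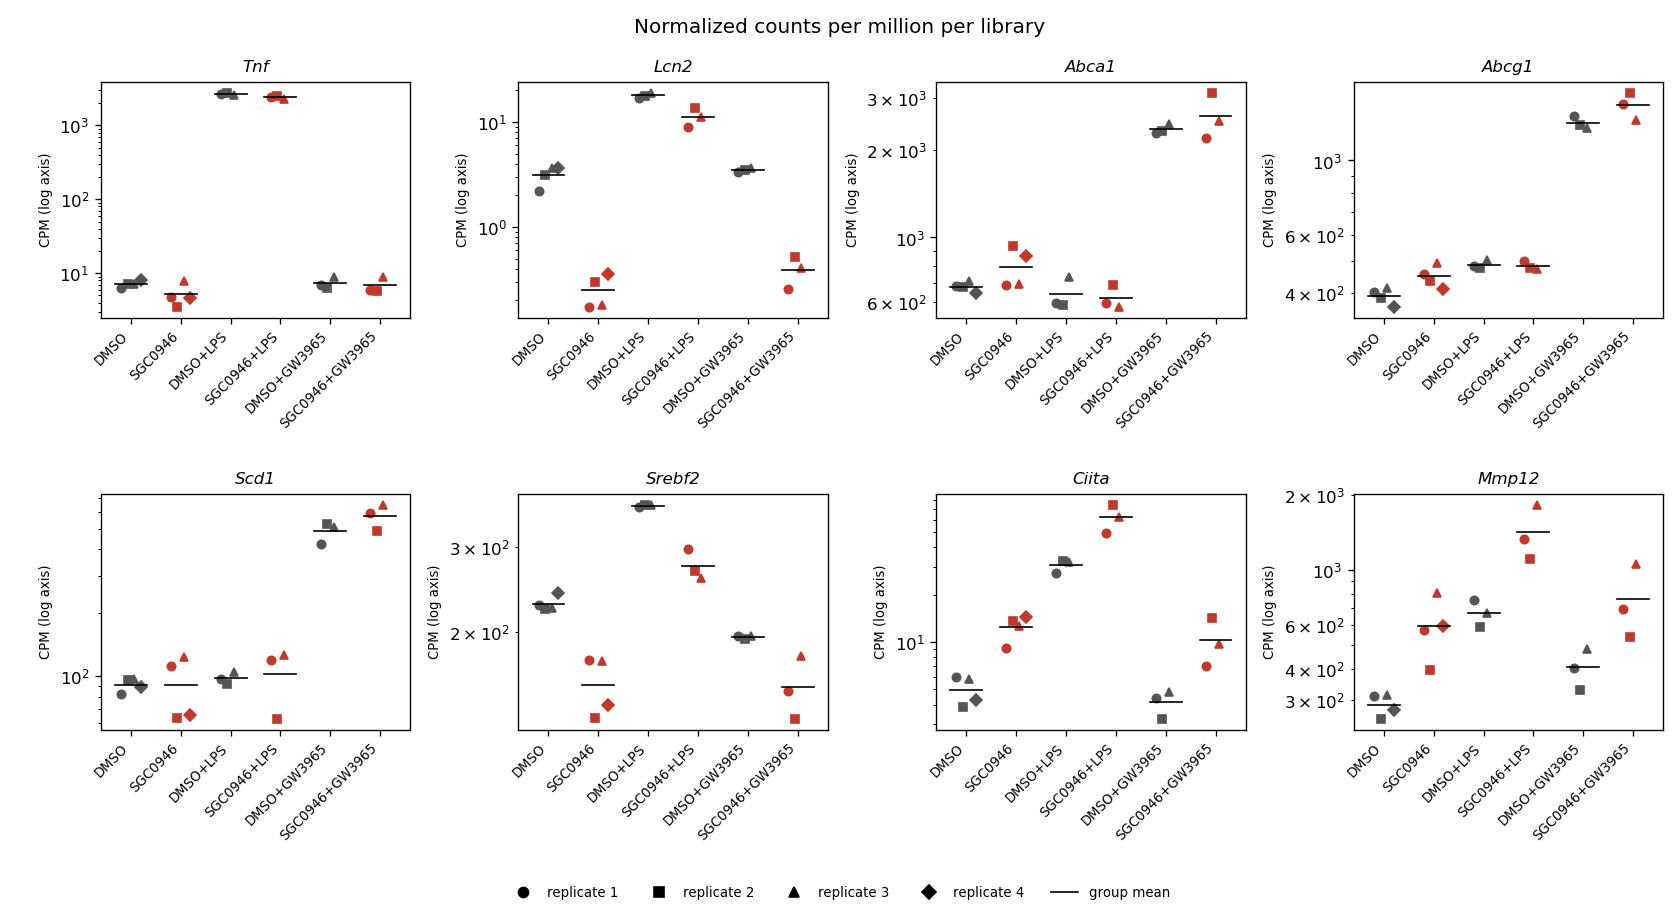
Level in CPM (log axis) of Tnf, Lcn2, Abca1, Abcg1, Scd1, Srebf2, Ciita and Mmp12 per library in the 6 groups, with marker shape for the replicate number and lines for group means. Lcn2 lay at 0.252 CPM in SGC0946 and 3.16 CPM in DMSO cells, while Abca1 lay at 2612 and 2357 CPM after GW3965 in the same order.

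GW3965 raised LXR targets and genes of fatty acid synthesis in DMSO cells and lowered interferon genes (n = 3 against 4). The interferon list, unlike the other 2, did not pass with an estimated correlation (adjusted p = 0.0895). The cholesterol exporter genes Abca1 and Abcg1 rose by 1.80 ± 0.11 and 1.72 ± 0.07, and the desaturase gene Scd1 rose by 2.42 ± 0.20. The chemokine gene Cxcl10 fell by 1.66 ± 0.28. Of 12013 genes 162 were higher and 144 lower (edgeR quasi-likelihood, adjusted p under 0.05; 531 genes with the replicate block), 27 and 20 of them by 2-fold or more.

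LXR targets had a median of 0.69 (camera adjusted p = 5.65e-48; adjusted p = 1.44e-06 with an estimated correlation), with 9 of 17 higher and none lower (10 higher adjusted over the list alone). Abcg1 reached 1295 ± 54.0 CPM (edgeR adjusted p = 6.13e-13), and Mylip, which encodes a ubiquitin ligase, rose by 1.60 ± 0.12 (adjusted p = 1.28e-08). Arl4c rose by 1.17 ± 0.08 (adjusted p = 4.15e-09). Fatty acid synthesis genes had a median of 0.29 (adjusted p = 8.72e-19; adjusted p = 0.00969 with an estimated correlation), and 8 of 20 rose. Scd2 rose by 1.58 ± 0.20, Acsl3 by 1.01 ± 0.12 and Elovl5 by 0.55 ± 0.06 (edgeR adjusted p = 7.53e-05, 1.6e-05 and 1.23e-05). Fasn rose by 1.53 ± 0.24 and Srebf1, a direct LXR target, by 1.49 ± 0.26 (adjusted p = 0.000848 and 0.00199). Cholesterol biosynthesis genes did not pass (median -0.05, adjusted p = 0.951), with Srebf2 at -0.23 ± 0.09 (edgeR adjusted p = 0.186; 0.00541 with only the compared groups).

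Interferon genes had a median of -0.70 (adjusted p = 2.09e-26; adjusted p = 0.0895 with an estimated correlation), with 15 of 36 lower (33 adjusted over the list alone; 29 with the replicate block). The DMSO libraries it was measured against lay far apart, with list medians of 0.51 in replicate 2 and -0.57 in replicate 4 relative to their mean. Without DMSO replicate 2 the median was -0.53 and without DMSO replicate 4 -0.87 (adjusted p = 6.45e-22 and 2.93e-51 at the preset correlation). Cmpk2 fell by 1.17 ± 0.25 and Mx1 by 1.11 ± 0.23 (edgeR adjusted p = 0.0123 and 0.00886), and Cxcl10 had an adjusted p of 0.00144. Mx1 no longer passed without DMSO+GW3965 replicate 2 (0.0811), and Cmpk2 without DMSO+GW3965 replicate 2 (0.0925) or 3 (0.0624). Alternative activation genes had a median of -0.23 (adjusted p = 0.00194; adjusted p = 0.0125 with an estimated correlation) and 2 of 17 fell. These were Cd163, the haemoglobin scavenger receptor gene, at -0.66 ± 0.13 and Stab1 at -0.52 ± 0.10 (edgeR adjusted p = 0.00854 and 0.00384). MHC class II genes had a median of -0.23 with no member called (adjusted p = 0.0367; adjusted p = 0.617 with an estimated correlation; 0.0738 with the replicate block). That call was also lost without DMSO replicate 1 (0.0907), DMSO replicate 3 (0.147) or DMSO+GW3965 replicate 2 (0.167). Among NF-kB genes 2 rose and 2 fell, or 1 with the replicate block (median 0.03, adjusted p = 0.297); Il1a rose by 2.19 ± 0.32 to 6.21 ± 0.542 CPM and Tnfaip2 by 0.60 ± 0.07 (edgeR adjusted p = 0.000327 and 9.3e-06). Tnf did not pass (0.03 ± 0.18, adjusted p = 0.962). The collagenase gene Mmp8 fell by 0.65 ± 0.10 (adjusted p = 0.00117). No marker of B, T, mast or stromal cells passed.

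The count of changed genes was 176, 155 and 175 without DMSO replicate 1, 2 or 3, and 125 and 122 without DMSO+GW3965 replicate 2 or 3. DESeq2 called 520 genes, and a fit of only the compared groups 888. The share of higher genes, 52.9% with TMM, was 36.1% with library totals only (129 higher, 228 lower).

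In SGC0946 cells GW3965 raised LXR and fatty acid genes as well (n = 3 against 4). Abca1 rose by 1.72 ± 0.11, Abcg1 by 1.70 ± 0.07 and Scd1 by 2.67 ± 0.21. Of 12013 genes 158 were higher and 133 lower (edgeR quasi-likelihood, adjusted p under 0.05), 30 and 19 of them by 2-fold or more. LXR targets had a median of 0.65 with 9 of 17 higher (camera adjusted p = 1.72e-53; adjusted p = 6.92e-07 with an estimated correlation), and adjusted over the list alone 12 rose and 1 fell. Fatty acid synthesis genes had a median of 0.33 with 9 of 20 higher (adjusted p = 5.24e-30; adjusted p = 0.00108 with an estimated correlation). Scd2 rose by 2.03 ± 0.21, Fasn by 1.93 ± 0.25 and Srebf1 by 1.58 ± 0.26 (edgeR adjusted p = 2.3e-06, 4.89e-05 and 0.00124). Mir5114, which lies within an exon of Scd2, rose by 1.84 ± 0.20 and cannot be counted apart from it. Mylip rose by 1.74 ± 0.12 and Acsl3 by 1.26 ± 0.12 (adjusted p = 4.63e-09 and 1.12e-06).

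Interferon genes had a median of -0.31 (adjusted p = 1.68e-08; adjusted p = 0.310 with an estimated correlation) and 3 of 36 fell, among them Cxcl10 by 1.60 ± 0.27 (edgeR adjusted p = 0.00152; 0.0777 with only the compared groups). Alternative activation genes had a median of -0.31 (adjusted p = 2e-04; adjusted p = 0.00384 with an estimated correlation) and 3 of 17 fell. Cd163 fell by 0.75 ± 0.14 (edgeR adjusted p = 0.00368; 0.0990 with only the compared groups) and Mmp8 by 0.89 ± 0.11 (adjusted p = 3.07e-05), while Tnfaip2 rose by 0.69 ± 0.07 (adjusted p = 1.12e-06). MHC class II genes had a median of -0.27 with no member called (adjusted p = 0.00115; adjusted p = 0.310 with an estimated correlation). Granulocyte genes had a median of -0.48 with 2 of 7 lower (adjusted p = 0.00038; adjusted p = 0.269 with an estimated correlation). Cholesterol (median 0.07), glycolysis (-0.09), cell cycle (-0.20), matrix (-0.08) and immediate early genes (-0.15) passed camera at the preset correlation (adjusted p = 0.0244, 0.0149, 0.0192, 0.0244 and 0.0244). With an estimated correlation none of these 5 passed (adjusted p = 0.602, 0.310, 0.625, 0.310 and 0.310). The cholesterol call was lost without SGC0946 replicate 2 (0.311) or 4 (0.276) or SGC0946+GW3965 replicate 1 (0.383) or 3 (0.341), and the glycolysis call without SGC0946 replicate 3 (0.0908) or SGC0946+GW3965 replicate 2 (0.214). Cell cycle was lost without SGC0946 replicate 1 (0.284) or 3 (0.574) or SGC0946+GW3965 replicate 2 (0.321), and matrix without SGC0946 replicate 4 (0.101) or SGC0946+GW3965 replicate 1 (0.356). Immediate early was lost without SGC0946 replicate 2 (0.0582) or 4 (0.0959) or SGC0946+GW3965 replicate 1 (0.211) or 2 (0.131). NF-kB genes had a median of -0.10 and a camera direction of up (adjusted p = 0.394), with 4 members higher, and Tnf did not pass (0.41 ± 0.20, edgeR adjusted p = 0.365; 0.0304 without SGC0946 replicate 3).

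The count of changed genes was 181 and 149 without SGC0946 replicate 2 or 4, 134 without SGC0946+GW3965 replicate 1 and 485 without SGC0946+GW3965 replicate 2 (236 shared with the 291). A fit of only the compared groups called 88, against 888 in DMSO cells. The similar counts of the main fit (291 and 306) thus depended on fitting all groups together. With library totals only the share of higher genes went from 54.3% to 39.2% (120 higher, 186 lower).

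The GW3965 response differed with SGC0946 for 0 of 12013 genes (edgeR quasi-likelihood), with 291 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. Differences were -0.08 ± 0.16 for Abca1, -0.02 ± 0.10 for Abcg1 and 0.40 ± 0.34 for Fasn (adjusted p = 1.00 for each). On simulated data 46.9% of genes with a 1.5-fold difference were recovered in this comparison.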

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

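The splits and the tests of explanations were chosen after results were seen, apart from leaving out DMSO replicate 2 for the interferon list; leaving out single libraries and estimating the correlation for each list were planned. For each comparison edgeR was rerun on the compared libraries with labels given to other splits of the same sizes, to ask whether chance gives as many genes. For SGC0946 in unstimulated cells the real split ranked 1 of 35, with 1143 genes against at most 0 elsewhere. Such a rank would exclude chance only if libraries were not paired by animal. The same holds for LPS in DMSO cells (rank 1 of 35, 8952 genes against at most 0) and in SGC0946 cells (rank 1 of 35, 8559 against at most 0). For GW3965 in DMSO cells the real split ranked 1 of 35, with 888 genes against at most 167, and the same limit applies. For SGC0946 under LPS and under GW3965 there are 10 splits, too few to exclude chance (rank 1 with 586 genes, and rank 1 with 164). GW3965 in SGC0946 cells ranked 2 of 35, with 88 genes against 638 in the highest split, so chance is not excluded for this count. That split put SGC0946 replicates 2 and 4 and SGC0946+GW3965 replicate 2 together, which points to a structure of the samples. The LXR list, tested apart from this count, passed there with an estimated correlation (adjusted p = 6.92e-07), and Abcg1 was at 1466 ± 137 against 450 ± 34.9 CPM (adjusted p = 7.54e-13). Libraries are paired by animal, and in each comparison with 35 splits only 7 others part as many pairs as the real one, too few to exclude chance. These called at most 167 genes for GW3965 in DMSO cells and 0 in the other 4 comparisons; the remaining splits keep more pairs together. The difference of LPS responses ranked 9 of 100, with 1 gene against up to 110, and that of GW3965 responses ranked 100 of 100, with 0 against up to 197, so chance is not excluded for either.

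Sterol genes were lowest in SGC0946 replicates 2 and 4, with list medians of -0.83 and -0.82 against -0.30 and -0.34 in replicates 1 and 3. If the animals of replicates 2 and 4 had low sterol genes without the inhibitor, their DMSO libraries would lie low. The lower of their medians was 0.0251, which argues against it for replicate 2. For replicate 4 it does so only if the numbers pair animals, which the correlation check did not bear out. If the fall of the whole list rested on these replicates it would vanish without them. The median was then -0.23 against -0.57 with all libraries, and 3 of 25 members were called lower against 18. Camera's adjusted p was then 1.04e-10. That value holds at the preset correlation of 0.01, far below the estimated one, so it cannot decide the question. Replicates 1 and 3 lay below every DMSO library of the same stimulus in the 3 conditions (highest -0.23). This argues against replicates 2 and 4 as the whole cause, though the 3 conditions share animals and are not independent. The list did not pass with an estimated correlation, with all libraries (0.121, correlation 0.588) or without replicates 2 and 4 (0.138). Why replicates 2 and 4 stand apart was not tested.

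Of the 7 measured genes of the fixed granulocyte list 5 fell with SGC0946, while Csf3r and Mmp8 stayed near their DMSO levels. A candidate explanation is that fewer granulocyte precursors were left in these cultures. Granulocyte genes outside the fixed list would then fall too. The 9 measured of 30 had a median of -0.20 (exactly -0.199), with 2 lower and 1 higher. By the bound written for this test, after results were seen, that median counts against the explanation. Members were called in both directions, which the bound did not foresee, so the explanation was left undecided. Padi4 went from 11.4 to 4.42 CPM and Serpinb1a fell by 0.80, while Lyz2 and Anxa1, which macrophages express as well, were at 8610 and 785 CPM against 9890 and 759 CPM. The outcome differed between choices: a shortened list of 23 genes, run first, left out genes already seen to rise and, in an unfiltered fit with a floor of 0.3 CPM, gave -1.36 over 10 genes, while the 28 genes without Cd24a and Mmp25, whose rise had been seen, gave -0.35 over 7. If cultures of 1 or 2 animals made the fall, others would not show it. Over all 7 measured members the highest median of the 4 animals was -2.14, which argues against it (-2.29 over the 5 called members, used first). These medians pair libraries by replicate number, which the check bore out only in part for replicate 3 and not for replicate 4. Against the mean of the DMSO libraries the highest SGC0946 median was -2.07.

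Interferon genes fell less under GW3965 with SGC0946 than without, with a median difference of 0.472 (mean 0.26, camera adjusted p = 1.33e-10). With a correlation estimated from the members (0.603) camera's unadjusted p was 0.111 and its adjusted p 0.882, a value that most lists of this comparison shared. The call thus depended on the preset correlation. None of the 36 members passed in edgeR, but neither did any other of the 12013 genes. These values cannot decide whether interferon genes moving together from library to library made the difference. High interferon genes in DMSO replicate 2 could make this difference; without that library the adjusted p was 0.00139 and the median 0.24, below the bound of 0.3 set beforehand, so the test left it undecided. Without all libraries of replicate 2 camera's adjusted p was 0.76.

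Other lists also differed between responses, by camera at the preset correlation, and none passed with an estimated correlation (adjusted p = 0.912 for LPS and 0.882 for GW3965). For LPS the median differences were -0.0891 for glycolysis (adjusted p = 0.00366), 0.177 for cell cycle (0.0151) and 0.113 for neutrophil genes (0.0185). The cell cycle difference was lost without DMSO replicate 4 (0.094), SGC0946 replicate 2 (0.504) or 4 (0.236), DMSO+LPS replicate 3 (0.167), or SGC0946+LPS replicate 1 (0.153) or 3 (0.82). That of neutrophil genes was lost without SGC0946 replicate 1 (0.221) or 3 (0.127), DMSO+LPS replicate 1 (0.136) or SGC0946+LPS replicate 2 (0.0881). For GW3965 they were 0.157 for cholesterol (adjusted p = 0.00899), 0.109 for fatty acid (0.0102), -0.111 for glycolysis (0.000263) and -0.194 for neutrophil genes (0.0193). Those of cholesterol and fatty acid genes were lost without DMSO replicate 4 (0.123 and 0.0611), SGC0946 replicate 2 (0.298 and 0.167) or 4 (0.401 and 0.232), or SGC0946+GW3965 replicate 1 (0.69 and 0.146) or 3 (0.307 and 0.119). Glycolysis was lost without SGC0946+GW3965 replicate 2 (0.0699). The neutrophil difference was lost without DMSO replicate 1 (0.0813), SGC0946 replicate 2 (0.0938) or 4 (0.506), or SGC0946+GW3965 replicate 1 (0.221) or 3 (0.105). The response of Lcn2 to LPS differed by 2.89 in log2, from a low baseline in SGC0946 cells.

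Single libraries stood far from the other 3 of their group by Dixon's test in 7 of 218 groups of named genes, where chance gives about 10.9. In DMSO replicate 1, Fads1 was at 198 CPM and Smpdl3a at 292 CPM. In DMSO replicate 4, Fasn was at 209 CPM and Scarb1 at 167 CPM. In SGC0946 replicate 4, Chil3 was at 2.49 CPM and Cxcl10 at 19.5 CPM, and in SGC0946 replicate 2 Ppp1r9a was at 31.7 CPM.

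Among the transcripts without a symbol, which were not tested, 1 held a larger share of counts in some SGC0946 libraries than in any DMSO library of the same stimulus. In unstimulated cells this was SGC0946 replicate 3 with 1.9708% (95% Wilson interval 1.9642 to 1.9775), against at most 1.7252% (1.7196 to 1.7308) in DMSO replicate 4. After LPS the 3 SGC0946 libraries had 1.8942% (1.8882 to 1.9003), 1.1402% (1.1356 to 1.1448) and 2.5537% (2.5454 to 2.562), against at most 0.6689% (0.6651 to 0.6728). After GW3965, SGC0946+GW3965 replicates 1 and 2 had 0.6973% (0.6935 to 0.7012) and 0.2827% (0.2802 to 0.2852), against at most 0.2808% (0.2784 to 0.2833). These intervals cover counting error only, and that of SGC0946+GW3965 replicate 2 overlaps the DMSO+GW3965 interval given beside it. SGC0946 replicate 4, with 0.0916%, lay below every unstimulated DMSO library (lowest 0.2981%). SGC0946+GW3965 replicate 3 had 0.1485%.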

How the results depend on the processing

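Scaling by library totals only, transcripts chosen by RPKM, leaving out replicate numbers and leaving out replicates 2 and 4 together were tests chosen after results were seen. Main results are given by value below. For the rest, over 13 alternatives named genes kept direction and side of the threshold in 3486 cases, were stronger in 32, weaker in 153 and reversed in 5; lists did so in 1711, 51, 69 and 2. Leaving out libraries or replicates gave 3256, 16 and 567 for genes with none reversed, and 1760, 34, 73 and 4 for lists. Over the alternatives other than leaving out 1 library or replicate, the adjusted p of granulocyte genes ranged from 1.64e-43 to 0.000605 in unstimulated cells, 3.08e-21 to 0.0137 under LPS and 4.97e-40 to 0.000202 under GW3965. Those of cholesterol genes ranged from 6.93e-18 to 0.121, 5.34e-19 to 0.170 and 8.31e-15 to 0.308, and of MHC class II genes from 2.08e-09 to 0.121, 1.79e-12 to 0.129 and 2.89e-09 to 0.254. For changes below, the cause was not tested except where stated.

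With an estimated correlation, lists of SGC0946 in unstimulated cells had adjusted p of 0.121 (cholesterol), 0.142 (fatty acid) and 0.121 (MHC class II). Under LPS these were 0.17 (cholesterol) and 0.129 (MHC class II), and under GW3965 0.308 (cholesterol), 0.464 (fatty acid), 0.464 (interferon) and 0.254 (MHC class II). Interferon genes had 0.329 and 0.423 for LPS and 0.0895 and 0.31 for GW3965, in DMSO and SGC0946 cells. By construction this test widens with the correlation of the members. Under LPS, fry passed cholesterol and MHC class II genes with SGC0946 (adjusted p = 0.0186 and 0.00708). Under GW3965 it passed MHC class II genes (0.0411). With fry, SGC0946 under GW3965 gave 0.0931 (cholesterol), 0.228 (fatty acid) and 0.248 (interferon), GW3965 in SGC0946 cells 0.147 (interferon), and osteoclast genes turned direction for LPS in DMSO cells (0.0181). Leaving out replicates 2 and 4 together gave 235 genes for SGC0946 in unstimulated cells and 178 for GW3965 in SGC0946 cells, 0.0312 for interferon and 0.278, reversed, for cell cycle genes with SGC0946 unstimulated. Fatty acid genes with SGC0946 under LPS passed with limma-voom (0.0475), no filter on low counts (0.0428), the stricter filter on low counts (0.0336), only the compared groups (0.0494) and the replicate block (0.0348). Interferon genes there passed with limma-voom (0.0232) and only the compared groups (0.00107). Fitting only the compared groups gave 164 genes for SGC0946 under GW3965, 888 for GW3965 in DMSO and 88 in SGC0946 cells. The replicate block gave 703 for SGC0946 under GW3965, 531 for GW3965 in DMSO cells and 6 for the difference of LPS responses. Beyond the calls given with it in the report, the block lost Nfkbia for GW3965 in DMSO cells (0.0603) and changed no other call of a list. DESeq2 gave 520 for GW3965 in DMSO cells and 37 for the difference of LPS responses, which also had 11 with no filter on low counts and 2 at equal depth. With library totals only LPS effects reversed to -0.060 (Srebf2), -0.42 (Abcg1) and -0.51 (Dot1l) in DMSO cells and to -0.64 (Abcg1) and -0.62 (Dot1l) in SGC0946 cells, by construction of the scaling. The correlations across conditions were 0.636, 0.717 and 0.533 for genes at log2 CPM 3 or more.

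Leaving out 1 library or 1 replicate number gave 339 to 1099 genes for SGC0946 in unstimulated cells, 308 to 796 under LPS and 136 to 454 under GW3965. It gave 56 to 343 for GW3965 in DMSO and 79 to 485 in SGC0946 cells, and 0 to 11 for the difference of LPS responses; that of GW3965 responses stayed at 0. Adjusted p for SGC0946 ranged from 3.62e-05 to 0.982 for interferon genes unstimulated (down without DMSO replicate 4, 0.0135, and without replicate 4, 0.0273), and 0.00747 to 0.564 for fatty acid genes under LPS. Under GW3965 it was 0.0086 to 0.175 for fatty acid, 0.0142 to 0.648 for LXR and 1.57e-10 to 0.0539 for interferon genes. Cell cycle genes with GW3965 in SGC0946 cells ranged from 4.5e-07 to 0.574 (reversed without SGC0946+GW3965 replicate 2, 0.321). For the difference of LPS responses the range was 0.0402 to 0.991 for cholesterol genes (reversed without SGC0946+LPS replicate 2, 0.0402) and 1.38e-06 to 0.735 for interferon genes (reversed without replicate 2, 0.0147). Cell cycle genes ranged from 7.65e-06 to 0.968 for that of GW3965 responses (reversed without SGC0946+GW3965 replicate 2, 0.00253). Fewer samples leave less power by construction, and the fits pool spread over groups. At equal depth, 8.17 M counts per library, only the difference of LPS responses moved by more than 1.5 times.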

Other observations

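No test was added for this part, and the genes below were picked for it after their values were seen, from those the rule allows. A few genes changed with the same sign under SGC0946 in the conditions given here for each. Plxdc2 rose by 1.68 ± 0.21 in unstimulated cells (n = 4 against 4), and under LPS it was at 37.4 ± 9.66 against 14.4 ± 2.17 CPM (n = 3 against 3). Htra1, a secreted protease gene, rose by 1.82 ± 0.21 in unstimulated cells and by 2.12 ± 0.27 under GW3965. Hk1 of glycolysis fell by 0.33 ± 0.07, 0.53 ± 0.08 and 0.46 ± 0.08 in unstimulated, LPS and GW3965 cells. Each had an adjusted p under 0.05 in edgeR's quasi-likelihood test, and no single library's removal changed this.

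LPS lowered Bmf, a pro-apoptotic BH3-only gene, by 6.86 ± 0.37 in DMSO cells and by 7.13 ± 0.34 in SGC0946 cells (n = 3 against 4 in each). Fam214a fell by 6.67 ± 0.16 in DMSO cells and fell by 6.44 ± 0.16 in SGC0946 cells. Sesn1, a stress-induced gene, fell by 5.81 ± 0.12 in SGC0946 cells.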
